A study of Drosophila melanogaster with 48 samples.

How the data were processed

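RNA-seq was used to measure gene expression in brains of Drosophila melanogaster. Per the labels, each sample held 20 brains that were flash frozen on dry ice right after dissection and homogenised with metal beads, ribosomal RNA was depleted, and libraries were made with the Tecan Universal Plus kit. There were 48 libraries in 16 groups of 3, given by genotype (NAGLU KO, W422X, Y160C or WG2), sex and age (week 0 or week 3). WG2 was taken as the control, because it is the genotype for which the labels name no NAGLU change. They do not say that it is the parental line of the mutants, so a difference of the WG2 line itself would appear in all 3 comparisons. The labels do not say whether replicates came from separate crosses or cultures, so p-values measure the spread between samples of 20 brains.

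The authors deposited raw read counts per gene, 1 column per library, with a gene length in bases beside them. The values were whole numbers whose totals differed between libraries, as unnormalised counts are. Subread is named in the submitters' processing notes without a version. The aligner, genome build, annotation release, strand setting and any read filter were not given in the sources used here. No column of the table belonged to other samples (0 columns). The table held 17490 gene identifiers, of which 17288 matched a symbol and a position in the BDGP6.54 annotation. The remaining identifiers are not named. Positions are those of BDGP6.54, found by gene identifier. Because the strand setting was not given, reads from where genes overlap, and reads of a small nucleolar RNA (snoRNA) and the intron that holds it, cannot be told apart. Counts of near-identical copies, such as the Hsp70 genes, the Su(Ste) repeats and the ribosomal RNA repeats, are uncertain for the same reason that a read can match several of them.

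Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr over the 16 groups (minimum count 10, minimum total count 15), which left 15807 genes tested and 1683 below the filter. Library sizes were scaled with TMM factors. Levels are CPM on these scaled library sizes, given as mean ± SD. A single quasi-likelihood model with a mean for each group (glmQLFit with robust=TRUE, 32 residual degrees of freedom) was fitted to all 48 libraries, and contrasts were tested with glmQLFTest. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. Every adjusted p given for a gene is from this edgeR test unless another tool is named. Log2 fold changes are given ± SE, where the SE is the log2 fold change divided by the square root of the F statistic. The contrasts were each mutant against WG2 over both sexes and ages, the same at week 0 and at week 3, the interaction of each mutant with age and with sex, the pairs of mutants, and age and sex within WG2.

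For gene lists, 37 lists with 1277 entries were written before the data were examined, as were the tests, the named-gene rule and the other settings tried, apart from those stated below. They cover heparan sulfate (HS) turnover and the lysosome, immunity and stress, mitochondria, neurons, synapses and senses, glia and other cell types or tissues, the germ line and sex, protein synthesis and degradation, and metabolism. Of the entries, 20 matched no gene. Lists with at least 4 tested members were tested with limma's camera on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the lists within a contrast. camera with an estimated correlation and fry were run beside it. fry asks whether the genes of a list move on balance in a single direction and does not compare the list with other genes.

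Genes are named by a fixed rule. For each mutant against WG2 these are Naglu, up to 8 called genes with the highest and 8 with the lowest log2 fold change among those with a mean of at least 1 CPM over the 24 libraries and the same sign in all 4 sex-by-age strata, and up to 2 called members of each list with the smallest p. For the overlap they are up to 10 genes called in the same direction in all 3 mutants. For age in WG2 they are up to 8 highest and 8 lowest called genes with the same sign in both sexes and up to 2 called members per list. For sex in WG2 they are up to 5 highest and 5 lowest called genes with the same sign at both ages, and called list members. For each interaction and each pair of mutants they are up to 5 called genes with the smallest p. Other genes that are named were chosen after their values were seen, and the text says so.

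The overlap of the mutants was compared with 5 simulations of unchanged mutants against the same WG2 libraries, with the overlap of independent lists, and with the overlap when WG2 was split into sets of 6 libraries so that each mutant had its own controls. The comparison across settings used separate simulations, a single one per setting. The edgeR step was tested on simulated data for KO against WG2 over 15807 genes. Of 100 genes changed 2-fold, 72% were called (84% of those raised and 60% of those lowered), and of 100 genes changed 1.5-fold, 74% were called (80% of those raised and 68% of those lowered). The genes drawn for the 2-fold changes had higher dispersions. Of 149 calls, 3 were false, and an unchanged W422X gave 0 calls.

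A background index was computed per library as the mean CPM per kb (on unscaled library sizes) over 4994 genes with a median under 0.3 CPM, after trimming 5% of them on each side. Libraries over 0.6 CPM per kb, 9 in all, are called high-background libraries. The other settings fixed beforehand were RLE size factors, no filter on low counts, DESeq2 1.42.0, a fit to the compared genotypes only, a block for the replicate number in the titles, a block for the tube number, covariates for photoreceptor and fat body genes, split WG2 controls, an estimated correlation in camera, and leaving out each library in turn. A covariate for the background index, a fit without the 9 high-background libraries and a fit without 2 KO female week 3 libraries (replicates 1 and 3) were added after the data were seen. Reads, alignments and protein or enzyme measurements were not analysed here. Total counts ran from 8690199 to 55801160 per library, and intervals between replicates cover both counting error and the spread between samples.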

Results

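Gene expression was measured in fly brains to ask how loss or alteration of Naglu changes it, and whether the change depends on sex and age. Naglu encodes the lysosomal enzyme that removes terminal N-acetylglucosamine from heparan sulfate, and its human counterpart is deficient in mucopolysaccharidosis IIIB. KO is named as a knockout, while W422X and Y160C are named for a stop codon and for an amino acid change in the protein. The 48 libraries formed 16 groups of 3, so that each genotype had 12 libraries, 6 at week 0 and 6 at week 3. Total counts ran from 8690199 in KO male week 3 replicate 3 to 55801160 in Y160C male week 0 replicate 2.

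Naglu was low in every KO and W422X library. Naglu (FBgn0014417, 2L:8408888-8411868) stood at 24.7 ± 3.39 CPM in WG2 (n = 12), 2.10 ± 0.79 CPM in KO, 6.66 ± 1.51 CPM in W422X and 21.2 ± 2.63 CPM in Y160C. By group of 3 libraries, KO had 1.74 ± 0.39 CPM in week 0 females, 2.48 ± 1.11 in week 3 females, 2.45 ± 1.09 in week 0 males and 1.71 ± 0.26 in week 3 males. In the same order the group means were 5.05, 8.18, 5.76 and 7.66 CPM in W422X, 19.2, 22.2, 20.5 and 22.8 CPM in Y160C, and 23.8, 27.2, 22.4 and 25.5 CPM in WG2. The log2 fold change against WG2 was -3.59 ± 0.12 in KO (adjusted p 4.86e-24) and -1.92 ± 0.11 in W422X (adjusted p 2.62e-16). In Y160C it was -0.22 ± 0.10 and was not called (adjusted p 0.606). KO also lay below W422X (log2 fold change -1.68) and below Y160C (-3.37), and W422X below Y160C (-1.69), each called. Which part of the gene the KO lacks was not given in the sources used here, so the reads that remain in KO were not assigned to a part of it.

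**Figure D1:**
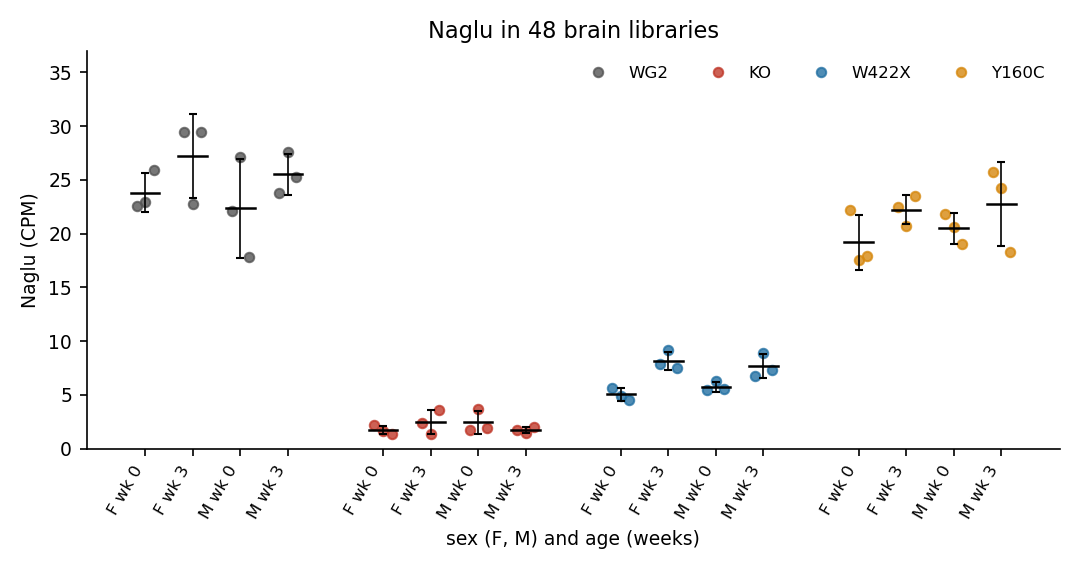
Naglu in CPM in each of the 48 libraries, by genotype, sex and age in weeks; bars are group means and error bars the SD of 3 libraries. KO libraries lie below all W422X libraries, and those below all Y160C and WG2 libraries.

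In KO brains, a protease gene, genes of the Hsp70 family and a small set of others stood above WG2 at both ages and in both sexes. CtsL2, named for the lysosomal protease cathepsin L, rose from 0.73 to 3.86 CPM (log2 fold change 2.42 ± 0.31, adjusted p 3.17e-06). The heat-inducible chaperone genes Hsp70Bbb (1.29, adjusted p 2.98e-08) and Hsp70Ba (1.249, adjusted p 1.60e-05) rose as well, Hsp70Ba from 2.06 ± 0.74 to 4.72 ± 1.14 CPM. CG8401 rose from 2.77 to 18.5 CPM (2.72 ± 0.12, adjusted p 2.09e-19). Lower genes included mthl8, a methuselah-like receptor gene (-0.87, adjusted p 1.74e-06), Pfas of purine synthesis (-0.55, adjusted p 1.26e-06), CG18327 (-0.50, adjusted p 0.0240), CG18661 (-0.51, adjusted p 0.000453) and the papilin gene Ppn (-0.65, adjusted p 0.00798). The call of CG18327 was lost with RLE size factors, with only the compared genotypes, without 2 KO female week 3 libraries (replicates 1 and 3), without the 9 high-background libraries (-0.51 to -0.45, adjusted p up to 0.155) and when any of 26 libraries was left out. Several changed genes lie near Naglu on chromosome arm 2L, among them dachs, an atypical myosin gene, at 21.7 ± 2.58 against 3.36 ± 2.54 CPM (2.96 ± 0.45, adjusted p 0.000156), a level it also reached in W422X female week 3 replicate 1 (23.04 CPM). The lipid synthesis gene Agpat2 was higher (0.90, adjusted p 1.54e-09, 27.08 against 14.52 CPM) and its neighbour Aasdh lower (-0.75, adjusted p 6.44e-10, 14.8 against 24.9 CPM).

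edgeR called 118 genes in KO against WG2, 79 higher and 39 lower, and 45 of them changed at least 2-fold. Without replicates 1 and 3 of the KO females at week 3 it called 29, 28 of them among the 118. Pvf1 (2.47), CG43291 (2.45), scpr-A (2.45), CG5597 (2.44), CG31441 (2.33) and the scavenger receptor gene emp (2.30) were called with those libraries and not without them, and 36 of the 118 genes stood out in those libraries. Ppn and Obp73a (1.79, adjusted p 0.0351) also lost their calls without them, though over all alternatives their fold changes stayed between -0.67 and -0.54 (Ppn) and between 1.40 and 1.84 (Obp73a).

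W422X brains shared the rise of CG8401 and CtsL2 with KO. CG8401 stood at 20.2 CPM (log2 fold change 2.85, adjusted p 9.00e-20) and CtsL2 rose by 2.38 (adjusted p 3.76e-06). The peroxiredoxin gene Prx6c fell to 1.248 from 4.161 CPM (-1.55 ± 0.24, adjusted p 6.73e-05), and the baramicin gene BaraC (-0.99, adjusted p 5.20e-07), the glycosyltransferase gene Ugt49C1 (-0.87, adjusted p 2.91e-07), the lectin gene lectin-24Db (-0.85, adjusted p 0.0158) and mthl8 (-0.80, adjusted p 7.90e-06) were also lower. The ceramidase gene bwa was higher at 62.18 against 42.03 CPM (0.57, adjusted p 5.70e-06), as were the BMP modulator gene cv-2 (0.51, adjusted p 1.44e-07), RpS21 (0.47, adjusted p 0.00167) and Hsp67Bc (0.38, adjusted p 0.0159). The gustatory receptor gene Gr58b had 9.82 ± 2.04 CPM against 1.42 ± 3.49 (4.14, adjusted p 1.08e-07), with a single WG2 library high. Further genes named by the rule were pre-lola-G (1.31), CG12898 (1.17) and lncRNA:CR43605 (1.19), which were higher, and asRNA:CR42547 (-1.37) and snoRNA:Psi18S-841b (-1.13), which were lower. edgeR called 59 genes, 39 higher and 20 lower, and 22 changed at least 2-fold.

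Y160C brains, in which Naglu RNA was not called, differed from WG2 in several snoRNAs and in a locus on 2L, among others. The pseudouridylation guides snoRNA:Psi28S-3436a (2.06, adjusted p 4.24e-17), snoRNA:Psi28S-1175a (1.86), snoRNA:Psi28S-3436b (1.78), snoRNA:Psi28S-3316d (1.55) and snoRNA:Psi28S-1175b (1.52) were higher, as was snoRNA:lola-c (1.52), while snoRNA:Tudor-SN-a was lower (-0.59). The channel-like neurogenic gene bib stood at 17.4 ± 2.34 against 39.9 ± 3.73 CPM (-1.198, adjusted p 8.28e-18), and lncRNA:CR13130, whose end overlaps it, at 0.98 ± 0.38 against 7.01 ± 1.08 CPM (-2.82, adjusted p 2.03e-16). The sterol-binding NPC2 family gene Npc2g fell by 0.99 (adjusted p 0.00553), and bwa was higher as in W422X (0.46, adjusted p 0.000369, 57.8 CPM). The stress-induced secreted peptide gene TotA (1.35, adjusted p 0.00122), CG34181 (1.62), CG15080 (1.53) and RpS21 (0.40) were higher, of which TotA was not called without the 9 high-background libraries (adjusted p 0.111, 1.31 to 1.37 over all alternatives) and RpS21 not in 3 alternatives (adjusted p up to 0.120, 0.37 to 0.45). Further, CG18661 (-0.51), CG5390 (-0.46) and jef (-0.39) were lower. edgeR called 49 genes, 37 higher and 12 lower, and 27 changed at least 2-fold.

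Age and sex were set against genotype to ask whether the mutant effects progress. TotA rose with age in the males of every mutant and stayed low in females. At week 3 TotA stood in males at 1.67 ± 0.29 CPM in WG2, 7.30 ± 0.999 in W422X, 32.46 ± 10.95 in KO and 61.31 ± 26.11 in Y160C (n = 3 each), and in females at 0.68, 0.83, 1.04 and 0.74 CPM. At week 0 the males of WG2, KO, W422X and Y160C had 0.919, 1.764, 1.247 and 2.832 CPM. The log2 fold change of TotA against WG2 was larger in males than in females by 3.30 in KO (adjusted p 0.000750) and by 4.15 in Y160C (adjusted p 3.39e-06). It was larger at week 3 than at week 0 by 2.92 in KO (adjusted p 0.00794) and by 2.57 in Y160C (adjusted p 0.0338). The difference between the sexes in Y160C held in every alternative (adjusted p up to 0.0215). KO by age lost its call with the photoreceptor and fat body covariates, without the same 2 KO libraries and without the 9 high-background libraries (adjusted p up to 1), and KO by sex lost it without the 9 (adjusted p 0.487). Y160C by age lost it in 4 alternatives (2.44 to 2.55, adjusted p up to 0.347) and when any of 25 libraries was left out. W422X was called for neither.

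**Figure D2:**
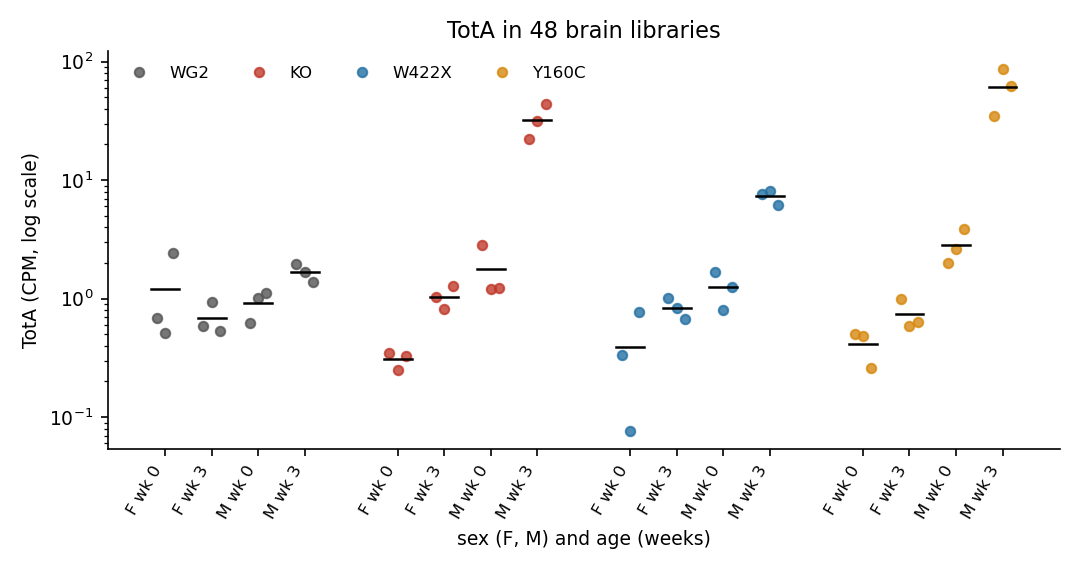
TotA in CPM (log scale) in each of the 48 libraries, by genotype, sex and age in weeks; bars are group means of 3 libraries. Week 3 males of KO (mean 32.46 CPM) and Y160C (mean 61.31 CPM) lie above all other groups.

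At week 0 edgeR called 21 genes in KO (15 higher, 6 lower), 27 in W422X (19 and 8) and 38 in Y160C (27 and 11). At week 3 it called 204 in KO (158 and 46), 29 in W422X (20 and 9) and 23 in Y160C (18 and 5), and the KO count was 9 without the same 2 libraries. By age, 34 genes differed in KO, of which 28 stood out in those 2 libraries, 3 in Y160C and 0 in W422X, where 207 genes had an unadjusted p under 0.05 and DESeq2 called 3. By sex, 24 genes differed in KO, 23 of them standing out in those libraries, 1 in Y160C (TotA) and 0 in W422X, where 622 had an unadjusted p under 0.05 and DESeq2 called 3. In Y160C by age, snoRNA:Psi18S-1377c (-1.60, adjusted p 0.000662) and pre-rRNA:CR45847 (1.89, adjusted p 0.0351) were the others called. In KO the remaining genes with a symbol named by the rule were Hml, CG13293 and lncRNA:CR46035 by age and alphaTub84D, CG9609 and Zip102B by sex, each from the set that stood out in the 2 libraries. Of those with no symbol in the reference used, the gene by sex was from this set and the gene by age was not.

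The mutants were also compared with each other. As each allele is present in a single line, these comparisons do not separate its effect from that of the line. KO differed from W422X in 118 genes (74 higher, 44 lower), from Y160C in 126 (77 and 49, but 24 and 32 without the 2 KO libraries and 28 and 40 without the 9 high-background libraries), and W422X from Y160C in 70 (30 and 40). Beside Naglu, KO and W422X differed in Agpat2 (0.94), Aasdh (-0.89), CG12560 (2.21, 4.89 against 1.08 CPM) and a gene with no symbol in the reference used (1.17). Agpat2, Aasdh and CG12560 lie within 1 Mb of Naglu. CG8401 separated both of these from Y160C (2.75 for KO and 2.88 for W422X), as did bib (1.158 and 1.246), lncRNA:CR13130 (2.69 and 2.70) and snoRNA:Psi28S-3436a (-2.05 and -1.97). Without W422X female week 3 replicate 1, the count for KO against W422X was 4460.

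A small set of genes changed the same way in all 3 mutants, which could come from the mutations or from WG2, as the labels do not say that WG2 is the line the mutants were made from. The hormone subunit gene Gpa2 rose from 1.196 CPM in WG2 to 2.439, 2.567 and 2.494 CPM in KO, W422X and Y160C (log2 fold changes 1.09, 1.17 and 1.13), and the glycosyltransferase gene Ugt36D1 from 10.08 to 16.03, 15.47 and 15.50 CPM (0.66, 0.62 and 0.62). CG9886 rose from 12.4 to 18.7, 19.3 and 19.7 CPM (0.59, 0.63 and 0.66). CG15394 (1.10, 1.37 and 1.13), l(2)37Bb (0.40, 0.50 and 0.38) and Ca-Ma2d (0.32, 0.43 and 0.33) were also higher. Without replicates 1 and 3 of the KO females at week 3 these 3 genes were no longer called in all 3 mutants (adjusted p up to 0.0941), though over all alternatives their log2 fold changes stayed between 1.015 and 1.501, 0.36 and 0.55, and 0.31 and 0.46. With only the compared genotypes in the fit, CG15394 lost its calls in KO (adjusted p 0.118) and Y160C (adjusted p 0.203), and in Y160C also without WG2 male week 3 replicate 2 (adjusted p 0.0540). Jheh3, an enzyme gene of juvenile hormone breakdown, fell from 25.47 to 16.99, 17.48 and 17.08 CPM (-0.59, -0.56 and -0.58), and dpr18, a neuronal immunoglobulin family gene, from 114 to 82.6, 84.0 and 87.5 CPM (-0.48, -0.44 and -0.37). Gpa2 is annotated on a scaffold not placed on a chromosome. Of 183 genes called in any mutant, 148 were called in a single mutant (92 in KO, 29 in W422X, 27 in Y160C), 27 in exactly 2 mutants and 8 in all 3.

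**Figure D3:**
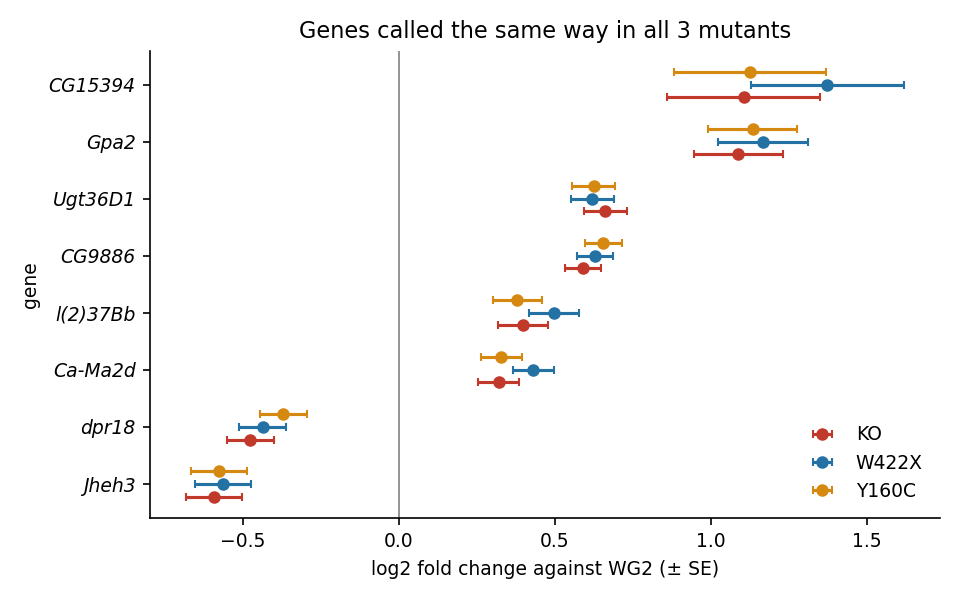
Log2 fold change against WG2 (± SE) of the 8 genes called in the same direction in KO, W422X and Y160C, 12 libraries per genotype. Jheh3 and dpr18 lie below 0 and the other 6 genes above 0 in each mutant.

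All 3 mutants were set against the same WG2 libraries, which alone makes their fold changes correlate. KO and W422X shared 13 higher and 8 lower genes, KO and Y160C 9 and 4, and W422X and Y160C 13 and 2, with 2 genes in opposite directions in the last pair. Simulated unchanged mutants shared 0 genes in each pair, and independent lists would share 0.195, 0.185 and 0.0913 higher and 0.0493, 0.0296 and 0.0152 lower genes. The simulation drew each gene by itself, without differences that span a library such as background. It may thus understate what unchanged libraries would share. Unchanged mutants also give few calls (0 for W422X in the simulated test of the edgeR step), so their overlap of 0 says little about lists of this size. With the WG2 libraries split so that no control was shared, the mean overlaps were 6.5 and 5, 3.5 and 1, and 8 and 1 genes (opposite 1 in the last pair). Across genes, which are not independent replicates, the fold changes correlated at r 0.419 (KO and W422X, simulated 0.492), 0.880 (KO and Y160C, simulated 0.501) and 0.451 (W422X and Y160C, simulated 0.505), and at 0.390, 0.715 and 0.388 with split controls. The covariances were 0.0908, 0.296 and 0.0863, against simulated 0.103, 0.104 and 0.105. Of the 9 high-background libraries 4 were KO and 3 Y160C, and without these 9 the covariance of KO and Y160C lay below that of a single simulation (difference -0.0474).

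Gene lists asked whether pathways moved together in the mutants. The list of HS lysosomal degradation, 9 genes including Naglu, was lower in KO (median -0.04, mean -0.43, camera adjusted p 0.00222, with an estimated correlation 0.162) and in W422X (camera adjusted p 8.68e-05, estimated 0.00911), and Naglu was the single member called in each. In Y160C its median was -0.06 (camera adjusted p 0.0235, estimated 0.636). The other lysosomal hydrolases and membrane proteins, 48 genes, gave no camera call in KO (adjusted p 0.909, where the median of -0.01 and the test pointed down and the mean of 0.25 up) and had Npc2g as their single call in Y160C (adjusted p 0.0422, estimated 0.636, median -0.04 and mean 0.16). HS synthesis and proteoglycan genes had a median of -0.10 in KO (adjusted p 0.000141, estimated 0.556). Nuclear respiratory chain genes had medians of -0.14 in KO (adjusted p 1.51e-09, estimated 0.556), -0.11 in Y160C (4.37e-11, estimated 0.636) and 0.06 in W422X (0.0496, estimated 0.986). In W422X, phototransduction genes had a median of 0.19 (adjusted p 8.84e-09, estimated 0.208), and the Y-linked genes one of -0.96 (adjusted p 8.84e-09, estimated 0.208) with 0 of 11 called. Of these kl-3, chosen after its values were seen, stood at 3.71, 23.9 and 2.72 CPM in the week 3 WG2 females, which have no Y, and at 0.16 to 1.10 CPM in the W422X females. In all, camera called 23 of 37 lists in KO, 11 in W422X and 22 in Y160C, and with an estimated correlation the HS degradation list in W422X was the one still called. As Naglu is its single called member, that call is no evidence on the other 8 genes.

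Mitochondrial genome genes fell with age in WG2, and relative to that their change with age was more positive in Y160C (13 genes, median of the interaction 1.40, 8 called when adjusted over the list alone, camera adjusted p 2.71e-15, estimated 0.126). The same held for haemocyte genes, of which some fell with age in WG2 (24 genes, median of the interaction 0.49, 4 called when adjusted over the list alone), and this list was still called with an estimated correlation (adjusted p 0.0389). No gene of these 2 lists was among the 3 called for Y160C by age over all tested genes. Camera called 16 lists in KO by age, 9 in W422X and 13 in Y160C, and the haemocyte list in Y160C was the one that held with an estimated correlation.

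In WG2 brains, week 3 was marked by lower RNA of mitochondrial, synaptic and neuronal genes, although no list was called for age when camera estimated the correlation between genes. The corazonin gene Crz rose from 46.9 ± 8.94 to 112 ± 13.5 CPM (log2 fold change 1.27, adjusted p 1.20e-09, n = 6 each), and NPF rose too (0.84), among neuropeptide genes of which 9 were called higher and 7 lower. Arc1, which encodes a capsid-forming protein at synapses, rose from 194 to 531 CPM (1.44, adjusted p 2.10e-08) and Arc2 by 1.02. The largest rises were in the lysosomal mannosidase gene LManIII (4.79, adjusted p 0.00589), 5SrRNA-Psi:CR33363 (4.19), the antennal gene a10 (3.92, adjusted p 4.29e-05), CG42876 (3.31), lncRNA:CR44650 (3.30), 5SrRNA:CR33451 (3.13), CG3251 (2.90) and CG17191 (2.69). The largest falls were in CG3906 (-6.01), CG34324 (-5.90), CG34220 (-5.19), the mucin gene Muc68D (-4.95), CG43673 (-4.61), CG7203 (-4.12, adjusted p 0.000419), pre-rRNA:CR45845 (-3.55) and the adult cuticle gene Acp1 (-3.21). edgeR called 1379 genes, 555 higher and 824 lower at week 3, and 170 changed at least 2-fold. The split into higher and lower genes depended on the processing. It was 1000 and 1002 with RLE size factors, 999 and 1126 with only WG2 in the fit, 575 and 437 without the filter and 1189 and 1146 with DESeq2. Higher genes outnumbered lower ones without the 2 KO libraries and without the 9 high-background libraries. Several of the largest changes rest on single libraries. Without WG2 male week 0 replicate 3, CG3906 (-2.58), CG34324 (-2.58), CG34220 (-2.26), Muc68D (-1.63) and CG43673 (-1.93) lost their calls (adjusted p 0.174 to 0.570), as LManIII did without WG2 male week 3 replicate 3 (1.95, adjusted p 0.225) and all 6 did with only WG2 in the fit. Of the others, a10, CG7203 and pre-rRNA:CR45845 kept their calls whichever library was left out, and the rest lost theirs without at least 1 library. The count was 770 without WG2 male week 0 replicate 2 and 2193 without KO female week 3 replicate 2.

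Among the lists, nuclear respiratory chain genes fell in WG2 with age (67 genes, 39 called lower and 56 when adjusted over the list alone, median -0.48, camera adjusted p 5.45e-30, estimated 0.396), with ATPsynC (-0.76) and blw (-0.80) among them. The mitochondrial genome's protein genes fell as well (13 genes, 8 called lower, median -0.79, adjusted p 8.77e-06, estimated 0.513, mt:CoIII -1.31 and mt:CoI -0.79). Synaptic vesicle release genes had 21 of 41 called lower (31 over the list alone, median -0.36, adjusted p 7.87e-22, estimated 0.396, AP-2mu -0.79 and Syx1A -0.54), and neurotransmitter synthesis and transport genes 13 of 27 (14 over the list alone, median -0.43, adjusted p 9.54e-13, estimated 0.396, Gad1 -0.89 and ple -0.65). Of 50 neurotransmitter receptor genes 22 were lower (nAChRalpha7 -0.53) and 1 higher (Ekar 0.97), with a median of -0.31 (adjusted p 3.03e-14, estimated 0.396). Neuronal identity genes (9 of 32 lower, median -0.26, adjusted p 3.84e-11, estimated 0.513, nrv3 -0.89, Syt1 -0.56) and V-ATPase genes (8 of 16 lower, median -0.38, adjusted p 6.06e-09, estimated 0.461, Vha68-1 -0.67, Vha55 -0.54) fell too. Cytosolic ribosomal protein genes had a median of 0.25 (adjusted p 6.06e-09, estimated 0.633, sta 0.77, RpS26 0.66). Of these 87 genes 3 were called higher, near the share over all tested genes (555 of 15807). None of these calls, and none of the 18 camera calls for age, held with an estimated correlation, while fry, which tests the list by itself, gave adjusted p 0.00989 for the respiratory chain and 0.00620 for synaptic release.

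Of the lysosomal genes 6 of 48 were higher with age in WG2 and 1 lower (median 0.22, adjusted p 0.0310, estimated 0.602, LManI 0.93 and Gal 0.73). Of the HS degradation genes Ids was called (0.59), and of HS synthesis genes sotv (-0.48, list median -0.11, adjusted p 0.0136, estimated 0.641). Neuropeptide genes had 9 of 46 higher and 7 lower (median 0.21, adjusted p 0.0277, estimated 0.513), heat shock genes 6 of 25 higher and 2 lower (Hsp68 1.01 and Hsp67Bc -1.08, adjusted p 0.0219, estimated 0.513), and oxidative stress and detoxification genes 10 of 110 higher and 5 lower (Cyp6a13 0.69 and GstE13 -0.54, adjusted p 0.0237, estimated 0.633). Lower were 3 of 24 haemocyte genes (Col4a1 -1.46 and vkg -0.95, list adjusted p 0.00393, estimated 0.461), 4 of 23 circadian clock genes (Pdp1 -0.36 and nmo -0.35, list adjusted p 0.0152, estimated 0.633) and 2 of 26 autophagy genes (list adjusted p 0.0411, estimated 0.767). The calls of nmo and of the 2 autophagy genes, and those of ths and Tm1 given below, were lost without the filter on low counts and without the 2 KO libraries named above. Of the ovary and eggshell genes 3 of 42 were higher (list adjusted p 0.0411, estimated 0.910). The Y-linked list had a median of 1.84 with 0 of 11 called (adjusted p 0.00935, estimated 0.602). Its gene kl-3, chosen after its values were seen, went from 0.69, 0.57 and 0.35 to 3.71, 23.9 and 2.72 CPM in females, which have no Y, and from 1.51, 0.63 and 1.39 to 1.03, 0.90 and 0.98 CPM in males.

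Camera did not call the remaining lists for age, though single members changed in WG2. At most 2 called members of a list are named, those with the smallest p, so they do not show which way other called members went. These were Dso1 (1.98) among antimicrobial peptides, Sting (1.07) and Tep2 (0.58) among immune recognition genes, Ggamma30A (-0.54) and rdgB (-0.36) among phototransduction genes (2 called higher and 6 lower), mal (0.53) among eye pigment genes, and wrapper (0.71) and Tsf1 (1.48) among glial genes, Tsf1 being also a fat body gene beside CG5966 (1.995). Muscle (Strn-Mlck 1.16, Tm1 -0.25), trachea and cuticle (Cpr62Bb -2.30), lipid (Lsd-1 1.15, AcCoAS -0.50), carbohydrate (Ldh 1.28, Treh 0.71), growth factor (ci 0.74, ths -0.35), olfactory (Obp99b 2.68, Obp8a 1.95) and dosage compensation genes (lncRNA:roX2 0.81, lncRNA:roX1 0.59) had called members as well. Testis genes had 2 called higher and 2 lower, sphingolipid genes 2 and 1, and activity-regulated genes 4 and 2. ER stress genes (24) and proteasome genes (43) had no member called among 15807 genes.

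**Figure D4:**
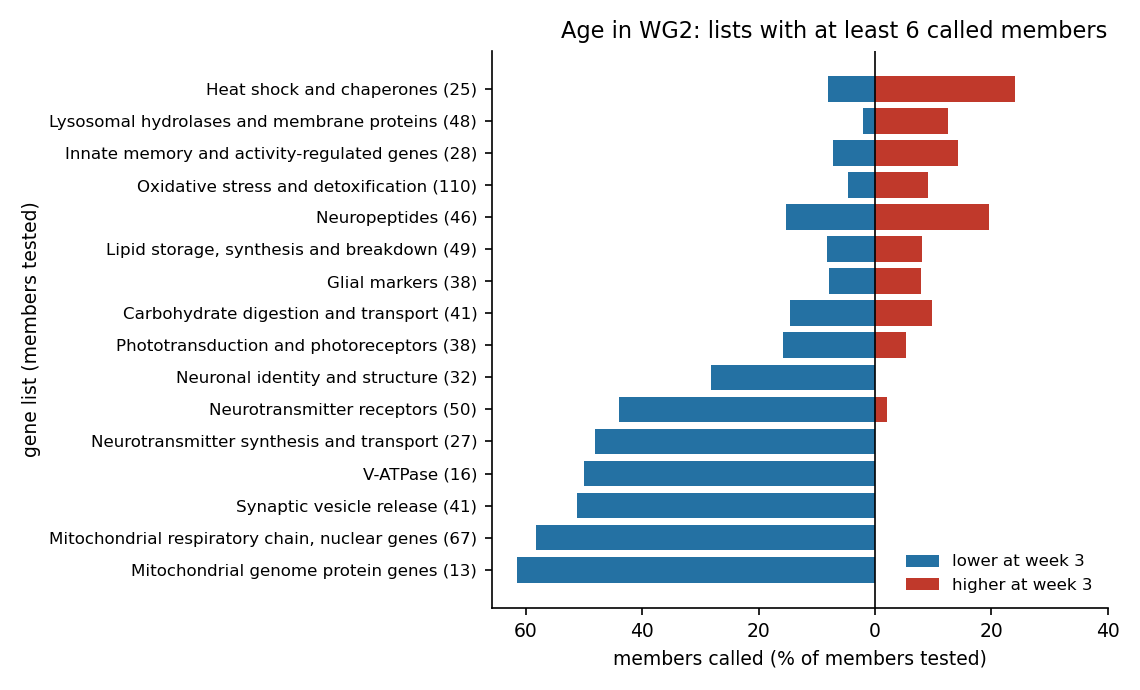
Percent of the tested members of each gene list called higher (right) or lower (left) at week 3 than at week 0 in WG2, for lists with at least 6 called members; the number of members is in parentheses. Mitochondrial, synaptic and V-ATPase lists have their calls on the lower side.

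In WG2, the sexes differed in dosage compensation, yolk protein and haemocyte genes. The male dosage compensation RNAs lncRNA:roX2 (log2 male over female 8.21, adjusted p 8.15e-28) and lncRNA:roX1 (7.17) were higher in males, as were the repeat RNAs Su(Ste):CR42425 (6.08), Su(Ste):CR42433 (5.70) and Su(Ste):CR42430 (5.43). The yolk protein genes Yp1 (-7.67, adjusted p 8.94e-13), Yp2 (-7.62) and Yp3 (-7.08), fit (-5.95) and CG15308 (-5.65) were higher in females. Haemocyte genes were lower in males (24 genes, 5 called, 11 when adjusted over the list alone, median -0.73, camera adjusted p 1.51e-13, estimated 0.00505), with PPO1 (-1.49), eater (-1.32), PPO2 (-1.24), NimC1 (-1.23) and Sr-CI (-1.08). The insulin-like peptide genes Ilp3 (-2.31) and Ilp5 (-1.01), the immune regulator gene dl (-1.27), the chitinase gene Cht2 (-3.43), Sxl (-0.67), GlcAT-I (-0.54), fru (-0.43) and N (-0.42) were also lower in males, and Obp99b (2.96), Dredd (0.43) and moody (0.42) were higher. Sex determination genes as a list were not called by camera (adjusted p 0.485), with the median and mean below 0 and fry pointing up. Nuclear respiratory chain genes had a median of 0.27 with 0 of 67 called (adjusted p 1.72e-20, estimated 0.553). edgeR called 147 genes, 67 higher and 80 lower in males, and 66 changed at least 2-fold.

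Libraries differed in counts on genes that are seldom detected in these brains. The background index was over 0.6 CPM per kb in 9 libraries, all of week 3, of which 6 were female and 3 male, and 4 KO, 3 Y160C, 1 W422X and 1 WG2. It was highest in W422X female week 3 replicate 1 (2.52), followed by Y160C female week 3 replicate 2 (1.57), and the highest of the other 39 libraries was 0.559, in Y160C male week 0 replicate 2. Comparisons of week 3 therefore set groups with unequal background against each other.

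**Figure D5:**
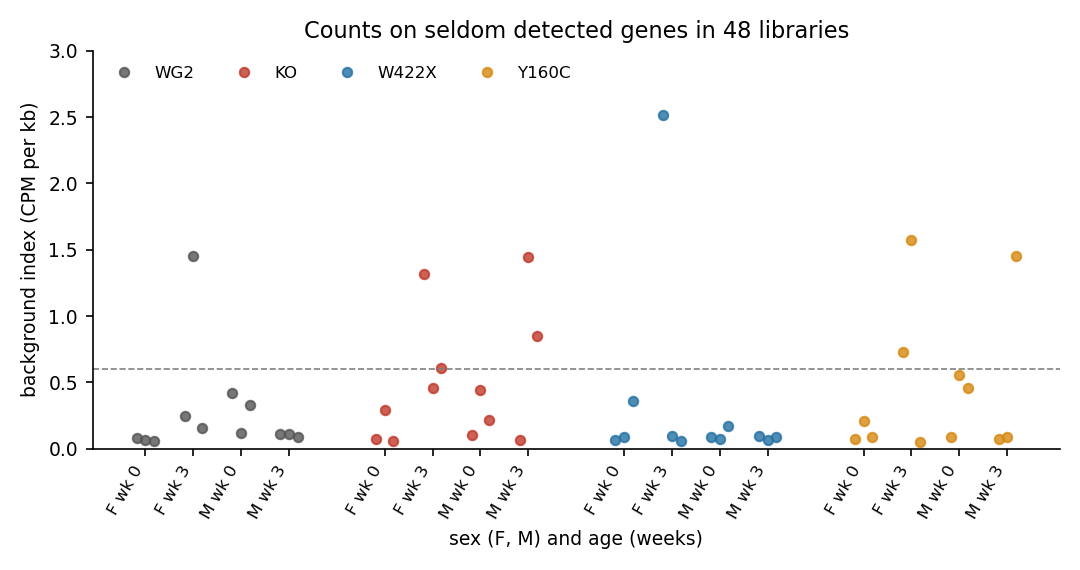
Background index (CPM per kb over seldom detected genes) in each of the 48 libraries, by genotype, sex and age in weeks; the dashed line marks 0.6. The 9 libraries above it are all of week 3.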

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

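The tests of the 2 KO libraries and of KO as the source of the outlying genes, of haemocytes in proportion to Hml, of library depth and fly age behind the background, and of variants near Naglu and loss of its RNA were chosen only after the results were seen.

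TotA stood out because its response to the mutations differed between sexes and ages. In KO the log2 fold change against WG2 was larger at week 3 by 2.918 (adjusted p 0.00794) and larger in males by 3.304 (adjusted p 0.000750), and in Y160C these differences were 2.569 (adjusted p 0.0338) and 4.148 (adjusted p 3.39e-06). TotA was higher in 3 of 3 week 3 males of KO, W422X and Y160C than in any week 3 male of WG2. The difference between the sexes in Y160C held in each alternative that was run (4.004 to 4.164, adjusted p up to 0.0215), while the other 3 lost their call in at least 1 of them, with fold changes about as large (KO by age 2.50 to 2.99, KO by sex 3.00 to 3.43, Y160C by age 2.44 to 2.58), and Y160C by age also when any of 25 libraries was left out. TotA belongs to a family of genes induced by stress and infection, and why it rose in males was not tested.

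In Y160C, the response to age also differed for snoRNA:Psi18S-1377c (-1.598, adjusted p 0.000662), which held in every alternative run (-1.66 to -1.39, adjusted p up to 0.00402), and for pre-rRNA:CR45847 (1.893, adjusted p 0.0351), which lost its call in 6 alternatives (1.81 to 1.94, adjusted p up to 0.169) and when any of 30 libraries was left out. In KO, Hml (3.027), CG13293 (3.169), lncRNA:CR46035 (3.604) and a gene with no symbol in the reference used (1.342) differed by age (adjusted p 0.0162 each). By sex, alphaTub84D (-3.265), CG9609 (-3.384), Zip102B (-3.487) and another gene without a symbol (-2.854) differed in KO (adjusted p 0.0109 each). Permuting genotypes did not exclude chance for these KO counts: 2 of 30 splits gave as many calls by age (real 34, highest other 37), and 5 of 30 by sex (real 24, highest other 38).

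The KO genes just named, apart from the unnamed one of the response to age, belong to 126 genes that stood more than 3 times above all libraries other than KO of week 3 in replicates 1 and 3 of the KO females at week 3, where they took 13.63% and 16% of the counts, against at most 0.432% in the other 46 libraries. In the other KO libraries of week 3, 5 of them were raised over 3 times in female replicate 2, and 0, 31 and 21 in male replicates 1, 2 and 3, at most 24.6%. In the mean of these 4 libraries it was 7.94%. Its binomial SE over the 126 genes, 2.41%, treats them as independent and does not measure the spread between libraries. With at most 24.6% raised in any of the 4, the values argue against an effect of KO shared by these samples. The counts followed the background index, which was 0.0637 in male replicate 1, 0.457 in female replicate 2, 0.852 in male replicate 3 and 1.44 in male replicate 2. Male replicates 2 and 3 were high-background libraries, so genes raised in them need not reflect KO. A property of the 2 libraries and a KO effect that varies between samples cannot be told apart. The tables argue against testis or accessory gland tissue as a whole (median log2 ratio of 46 genes 0.242, spread 0.0632). The spread is the interquartile range over genes divided by the square root of their number, not an error between libraries. Still, kl-3 (19.8 and 30.9 CPM, against 0.54 in female replicate 2), Dhc93AB and Sfp24Bc, chosen after their values were seen, were high. But kl-3 was also high in female week 3 libraries of WG2 (replicate 2, 23.9 CPM) and Y160C (replicate 1, 10.3 CPM). The tables also argue against haemocytes in the proportion Hml would need. The 4 other haemocyte genes of at least 100 CPM rose by at most 0.280, while Hml rose by 6.37. Haemocytes as a smaller part of the pattern cannot be told apart from none (median log2 ratio 0.324, spread over genes 0.205, 23 genes). A source outside the lists stays open and was not tested.

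In 9 libraries of week 3, genes that are otherwise silent had counts across the genome. In the 6 female libraries the density on X relative to autosomes was 1.06 ± 0.0896 and in the 3 male ones 0.592 ± 0.0103, a ratio of 1.79 (exact permutation test, two-sided p 0.0119, 84 groupings, 535 X-linked and 4246 autosomal genes), which is consistent with reads from genomic DNA, as males have a single X. Library depth is argued against, as the background did not follow the total count (Spearman rho -0.0903, permutation p 0.540, 48 libraries). Age as the only source is argued against too, as in the 12 males of week 0 the density on X fell as the background rose (Spearman rho -0.874, permutation p 0.000400; in the 12 females of week 0 rho -0.546, p 0.0708), so week 0 libraries carry it as well, up to an index of 0.559. Why the highest values were at week 3 was not tested, and with 4 of the 9 KO and 3 Y160C, comparisons at week 3 carry this difference.

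Of 183 genes called in any mutant, 148 were called in a single one, 92 of them in KO. Of the 118 genes called in KO, 36 stood out in the 2 outlying KO female libraries described above. Part of the KO count may thus come from those libraries, and the test near Naglu below was not repeated without these genes. The calls in a single mutant may also reflect variants carried along with each edited chromosome rather than Naglu. In KO, 10 of 114 called genes with a position lay within 1 Mb of Naglu (CG7231, Tg, CG12560, Agpat2, CG18661, Aasdh, Argl, CG34134, dachs and CG43394), against 281 of 15643 tested, an enrichment of 4.88-fold (Fisher's exact test, two-sided p 3.92e-05), as such variants would give, though a local effect of the edit itself was not tested. In W422X it was 0 of 58 (0-fold, with an upper 95% limit of the odds ratio of 3.60) and in Y160C 2 of 49 (2.27-fold, p 0.220), too few to decide. Loss of the Naglu RNA was tested on the 21 other genes that changed at least 2-fold in W422X, of which 28.6% (6) were called the same way in KO and 5 in Y160C, which keeps its RNA. The lines' backgrounds and the alleles cannot be told apart for these genes, since each allele is present in a single line.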

How the results depend on the processing

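The background covariate and the fits without the 9 high-background libraries or without the 2 KO female week 3 libraries (replicates 1 and 3) were chosen only after the results were seen, and the other settings were not. The 9 include those 2. Without the 9, KO females, KO males and Y160C females of week 3 are each a lone library, assumed to vary like the other groups. Changes in that fit therefore cannot be credited to background alone.

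Of 198 values of named genes, 197 kept direction and call with RLE size factors, 187 without a filter on low counts, 163 of 197 with only the genotypes compared, 186 with the photoreceptor and fat body covariates, 196 with the background covariate, 162 without the 2 libraries and 172 without the 9, and with DESeq2 all 195 that it gave. Naglu kept its direction and its calls in KO and W422X in each of them (log2 fold change -3.83 to -3.54 in KO and -1.95 to -1.88 in W422X). Leaving out each library in turn kept 9253 of 9504 values. For Obp73a, CG18327, CG5390, scpr-A and pre-rRNA:CR45847 at least 16 libraries ended the call when left out, and for Y160C the calls of CG15080 (Y160C female week 3 replicate 2, Y160C male week 3 replicate 3) and CG15394 (WG2 male week 3 replicate 2) ended without the libraries named. That of jef in Y160C ended without any of 5 libraries (Y160C female week 0 replicate 2, female week 3 replicate 1 and male week 0 replicate 2, WG2 female and male week 0 replicate 2; adjusted p up to 0.0853). In W422X those of Hsp67Bc (W422X female week 3 replicate 3 and male week 3 replicate 1, WG2 female week 3 replicate 1 and male week 3 replicates 2 and 3; up to 0.0892) and lectin-24Db (the same 2 W422X libraries and WG2 female week 0 replicate 3; up to 0.0577) ended too. With only the genotypes compared, Hsp67Bc and snoRNA:Psi18S-841b in W422X (adjusted p 0.0681 each) and RpS26 by age (0.0502) were not called, and the calls by age of RpS26 (1 library), Ids (2), Obp99b (2), Sting (4) and Dso1 (6) ended without single libraries (adjusted p up to 0.123). RLE size factors and the missing filter moved no total count by more than 1.5 times, but the split of age in WG2 into 555 higher and 824 lower genes did not hold. It was 1000 and 1002 with RLE size factors, 575 and 437 without the filter and 1189 and 1146 with DESeq2. Higher genes outnumbered lower ones without the 2 KO libraries and without the 9 libraries. KO against Y160C had 24 and 32 without the 2 and 28 and 40 without the 9, against 77 and 49, and sex 2384 and 1228 with the photoreceptor and fat body covariates, against 67 and 80.

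DESeq2 called more genes: KO 257, W422X 94 and Y160C 94; at week 0 KO 56, W422X 59 and Y160C 79; at week 3 KO 512, W422X 52 and Y160C 66; by age KO 86, W422X 3 and Y160C 28; by sex KO 63, W422X 3 and Y160C 2; KO against W422X 240, KO against Y160C 207, W422X against Y160C 118; age 2335 and sex 274. Its overlaps were 39 (KO and W422X), 34 (KO and Y160C), 27 (W422X and Y160C) and 16 for all 3. Of the 118 KO genes, 117 were among the 257. Y160C had 58 higher and 36 lower genes with DESeq2, against 37 and 12. The cause was not tested.

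With only the genotypes compared in the fit, fewer libraries set the spread, and the counts were KO 55, KO at week 3 309, KO by age 1, Y160C by age 5, KO by sex 1, KO against W422X 42 and age 2125. With the photoreceptor and fat body covariates they were KO 396, KO at week 0 54, W422X at week 3 49, Y160C at week 0 70, KO by age 0, Y160C by age 1, KO by sex 13, Y160C by sex 2, KO against W422X 679 and sex 3612. The cause was not tested.

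The replicate numbers do not pair the samples: deviations from the group means correlated at -0.0145 between libraries with the same number and 0.00571 with another, and 16 of 48 libraries were closest to their own number. A block for the replicate number in the titles moved no count by more than 1.5 times (KO 99, age 1297). A block for the tube number (mean correlation -0.0152 against 0.00361) gave 16 genes for KO by age and 1 for KO by sex.

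With the background covariate, the counts were W422X 129, Y160C 94, KO at week 0 55, W422X at week 0 61 and week 3 70, Y160C at week 0 96 and week 3 51, Y160C by age 13 and by sex 2, W422X against Y160C 114, age 2957 and sex 549, with overlaps of 48 (KO and W422X), 35 (KO and Y160C), 38 (W422X and Y160C) and 23 for all 3. Without the 9 libraries they were KO 54, W422X 92, KO at week 0 48 and week 3 14, W422X at week 0 53 and week 3 49, Y160C at week 0 61, KO by age 0, Y160C by age 1, KO by sex 0, KO against W422X 66, KO against Y160C 68, age 2388, sex 275, and 24 shared by W422X and Y160C. Without the 2 KO libraries, in which KO females of week 3 are a lone library assumed to vary like the other groups, they were KO 29, KO at week 3 9, KO by age 0, Y160C by age 1, KO by sex 1, KO against W422X 45, KO against Y160C 56, and overlaps of 13 (KO and W422X) and 8 (KO and Y160C). Of the 118 KO genes 28 were kept without the 2 libraries and 42 without the 9, with fewer KO libraries in both. With split WG2 controls the overlaps were 11.5 (KO and W422X), 4.5 (KO and Y160C) and 9 (W422X and Y160C), where each comparison had fewer controls.

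In KO by sex, alphaTub84D (0.07209), CG9609 (0.06712) and Zip102B (0.1235) reversed without the 9 libraries, and Zip102B (0.03878) without the 2, as the 2 libraries that raised them are absent from both fits. Depth limits what can be said of the 1683 genes below the filter, which were not tested.

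Of 123 list calls, 8 were lost with RLE size factors, 10 without a filter, 19 with only the genotypes compared, 2 with the replicate block and 18 without the 2 libraries, with no reversal. With the photoreceptor and fat body covariates 31 were lost and 14 reversed, with the background covariate 53 and 6, and without the 9 libraries 37 and 14. With an estimated correlation 3 of the gene set tests were called. The direction of the test reversed without the 9 libraries for these lists, given with their median log2 fold change: in Y160C synaptic vesicle release 0.01726, neurotransmitter synthesis -0.001845, receptors 0.02951, neuronal identity 0.04069, trachea -0.1348 and ovary 0.02181; in KO by age autophagy 0.02217, synaptic vesicle release 0.02052 and neuronal identity 0.04581; in Y160C by age heat shock -0.0107, trachea -1.146, ribosomal -0.0292 and olfactory -0.6377; and glial 0.06868 for sex in WG2. With the background covariate it reversed in Y160C for receptors 0.01135 and neuronal identity 0.02096, and in KO by age for V-ATPase -0.001275, ER stress 0.05826, synaptic vesicle release 0.04528 and neuronal identity 0.0587. With the photoreceptor and fat body covariates it reversed in KO by age for V-ATPase -0.01414, autophagy 0.02396, ER stress 0.06786, synaptic vesicle release 0.08626, phototransduction 0.04583, neuronal identity 0.1117 and testis 0.0881; in W422X by age for phototransduction 0.02836; in Y160C by age for trachea -0.1156; and for sex in WG2 for V-ATPase 0.03333, synaptic vesicle release -0.1082, neurotransmitter synthesis 0.02573, glial 0.009963 and proteasome -0.0597. The causes were not tested.

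Leaving out each library in turn gave KO 79 to 238 (238 without KO female week 3 replicate 2, 184 without WG2 female week 3 replicate 2), W422X 48 to 73, Y160C 47 to 61, KO at week 0 17 to 31, W422X at week 0 21 to 34 and week 3 20 to 34, Y160C at week 0 26 to 45 and week 3 16 to 33, sex 109 to 216 and W422X by age and by sex 0 to 0. KO at week 3 gave 107 to 523: 117, 321 and 107 without KO female week 3 replicates 1, 2 and 3, 131 without KO male week 3 replicate 2, 335 without W422X female week 3 replicate 1 and 523 without WG2 female week 3 replicate 2. KO by age gave 15 to 123: 21, 123 and 15 without KO female week 3 replicates 1, 2 and 3, 19 without KO female week 0 replicate 3, 22 and 20 without KO male week 0 replicates 2 and 3, 21 without KO male week 3 replicate 2, 21 and 20 without WG2 female week 3 replicates 1 and 2, and 18 and 20 without WG2 male week 3 replicates 2 and 3. KO by sex gave 12 to 110: 15, 110 and 12 without KO female week 3 replicates 1, 2 and 3, and 14 without KO female week 0 replicate 3, KO male week 0 replicate 2 or 3, KO male week 3 replicate 3, any WG2 female of week 0 or WG2 female week 3 replicate 2. Y160C by sex gave 1 to 2 (2 without W422X female week 3 replicate 1 or WG2 male week 3 replicate 2), and Y160C by age 1 to 5: 5 without W422X female week 0 replicate 3 or Y160C male week 3 replicate 1, and 1 without replicate 2 of the week 3 KO females or KO males, replicates 2 and 3 of the W422X females and all W422X males of week 3, all Y160C females of week 0, replicates 2 and 3 of the Y160C females of week 3, 1 and 2 of the males of week 0 and 2 and 3 of the males of week 3, or, in WG2, replicate 3 of the females and 2 and 3 of the males of week 0 and replicates 1 and 3 of the females and of the males of week 3. KO against W422X gave 91 to 4460 (4460 without W422X female week 3 replicate 1, 232 without KO female week 3 replicate 2), KO against Y160C 98 to 243 (243 without KO female week 3 replicate 2) and W422X against Y160C 61 to 155 (155 without W422X female week 3 replicate 1). Age in WG2 gave 770 to 2193: 770 without WG2 male week 0 replicate 2, 915 without WG2 female week 0 replicate 2, and 2069 to 2193 without any of 11 week 3 libraries of the mutants (KO female 2, KO male 1 and 2, W422X female 2 and 3, W422X male 2 and 3, Y160C female 2 and 3, Y160C male 1 and 2), which enter that contrast through the shared spread, scaling and filter on low counts. The gene set tests gave 106 to 154 calls. The list medians whose test reversed without a library ranged from -0.003883 to 0.1241 (respiratory chain in W422X, reversed without W422X female week 3 replicate 3 or WG2 female week 3 replicate 2), -0.01828 to 0.1513 (receptors in W422X by age, W422X female week 3 replicate 2 or 3), 0.003343 to 0.1524 (glial in Y160C by age, WG2 female week 3 replicate 2), -0.08481 to 0.9148 (trachea in Y160C by age, Y160C male week 3 replicate 3) and 0.05917 to 0.1831 (glial for sex in WG2, WG2 female week 3 replicate 2).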

Other observations

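The comparisons of shared fold changes with the background covariate and without some libraries were chosen only after the results were seen, as were the genes said to be so chosen, and the tests by permutation were not.

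KO and W422X, the lines with little Naglu RNA, shared calls that were not made in Y160C, which by itself does not show that Y160C differed. Chosen after their values were seen, CG8401 (Y160C log2 fold change -0.03, adjusted p 0.938) and CtsL2 (0.84, adjusted p 0.606) changed most among them apart from Naglu, and mthl8, Pfas, CG18327, slmo, Orc5, CG15084, CG16935, pre-lola-G, CG8323 and insv are the others. Of these, CG15084 (0.42) and insv (-0.35) changed in Y160C nearly as much as in KO (0.44 and -0.43). Whether the shared calls come from low Naglu RNA or from variants that KO and W422X have in common was not tested. The test within 1 Mb of Naglu does not address variants farther away.

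Whether chance could give as many calls was asked by permuting the genotypes within sex and age, with the real grouping counted among 30 splits. For KO against WG2, 1 of 30 splits gave as many genes, the real one (118, highest other 36), and the same held for W422X (1 of 30, 59 and 1) and Y160C (1 of 30, 49 and 0). At week 0 it held for KO (1 of 30, 21 and 2), W422X (1 of 30, 27 and 0) and Y160C (1 of 30, 38 and 7), and at week 3 for KO (1 of 30, 204 and 137), W422X (1 of 30, 29 and 0) and Y160C (1 of 30, 23 and 0). It also held for KO against W422X (1 of 30, 118 and 34), KO against Y160C (1 of 30, 126 and 36) and W422X against Y160C (1 of 30, 70 and 2). Of the 204 KO genes at week 3, 88 stood out in replicates 1 and 3 of the KO females at week 3, as did 36 of the 118 over both ages. For these genes the permutations do not tell an effect of KO from those 2 libraries. For Y160C by age (1 of 30, 3 and 0) and by sex (1 of 30, 1 and 0) the real counts were the highest too, but so few calls say little, as a split for W422X by sex gave 10. For W422X by age (30 of 30, 0 and 0) and by sex (30 of 30, 0 and 10) there were no edgeR calls to test, with 207 and 622 genes at an unadjusted p under 0.05 and 3 DESeq2 calls each. In WG2 the real grouping, counted among 25 splits of the 12 libraries, gave the most calls for age (1 of 25, 1379 and 361) and for sex (1 of 25, 147 and 8). So few splits make chance less likely without excluding it.

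Shared fold changes were compared with those of simulated unchanged mutants, with a single simulation per setting, separate from those in the results. The differences therefore have no measured spread, and the sign of a small one says little. For KO and W422X with all 48 libraries, the difference was -0.0126 with the simulations in the results and -0.0171 here. With all 48 libraries the covariance of KO and Y160C exceeded the simulated one by 0.189 (0.296 against 0.107), and those of KO and W422X (-0.0171) and W422X and Y160C (-0.0197) did not. In the same order the differences were 0.0157, 0.0249 and 0.0197 with the background covariate, 0.142, -0.00851 and -0.0195 without the 2 KO libraries, and -0.0474, -0.0342 and 0.0117 without the 9 high-background libraries. The excess of KO and Y160C may thus come mostly from those 9 libraries, in which the ratio of 1.79 was consistent with genomic DNA.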
